A study of Pseudomonas putida KT2440 with 6 samples.

How the data were processed

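Pseudomonas putida KT2440 is a soil bacterium that takes up organic acids and sugars by different routes. RNA was sequenced from 3 strains, with 2 libraries each: wild type, a strain with the tet marker inserted in crc, and a strain in which crcZ and crcY, the genes of 2 small RNAs, carry markers, tet among them. Crc is a repressor of the use of secondary carbon sources, and CrcZ and CrcY are small RNAs that counteract it. Per the labels' protocols, cells grew at 30 °C in M9 minimal medium with trace elements, 20 mM succinate and 20 mM glucose. They were collected in mid-exponential growth at an absorbance of 0.6. Total RNA was purified on columns and treated with DNase, and ribosomal RNA was removed before the RNA was fragmented for an Illumina library, per the labels' protocols. The wild type was the reference for both mutants, and the mutants were also set against each other.

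The values are RPKM, per the file headers, a unit that scales the reads of a coding sequence by its length and by the total reads of the library, with no column of counts. CASAVA 1.8 is named in the submitters' processing notes. The aligner, the counting tool and the treatment of strand are not given in the sources used here, so reads of overlapping or antisense coding sequences and of near-identical copies cannot be assigned with certainty. The files name each coding sequence by its position on version 3 of the KT2440 chromosome record and do not pair positions with gene names. Of the 5259 identifiers, 0 matched an entry among the 5723 genes of the RefSeq gene table used here, so no gene names are given. For the same reason the disrupted genes were not checked in these libraries, and the gene lists fixed before the data were examined were not tested. All 5259 lengths are multiples of 3 (96 to 26049 bp, median 873 bp), so they are coding lengths. Positions are 1-based.

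Each deposited RPKM value times the coding length was a whole multiple of what 1 read was worth in that library, within 0.001 reads for 100% of values. The multiples summed to between 7950012 and 8744531 reads per library. These read numbers gave the depth and were not the basis of the main test. A coding sequence missing from a library's list was set to 0, since the lists held only values above 0. For a coding sequence of 1 kb, 1 read equalled 0.114 to 0.126 RPKM. The median coding sequence had 266 to 308 reads in a library, and 165 to 235 coding sequences per library had under 10 reads.

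Values were analysed as log2(RPKM + 1). Coding sequences with at least 1 RPKM in at least 2 libraries were tested, which left 5235. All 6 libraries were fitted together with strain as the only term in limma 3.58.1 under R 4.3.3, with a mean-variance trend and 3 residual degrees of freedom. A coding sequence was called at a Benjamini-Hochberg adjusted p under 0.05. Log2 fold changes, and the counts at least 2-fold or 4-fold, are on the log2(RPKM + 1) scale, which understates the change of low values. Folds given for regions without log2 are ratios of mean RPKM with nothing added. Nothing in the labels says that the 2 libraries of a strain came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. The test, samples, threshold and most alternatives were fixed before the data were examined, with limma planned for values given as RPKM and a count model for counts.

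The same code was tested on simulated data for the crc mutant against wild type, with known changes among 5234 tested coding sequences. It recovered 44 of 100 changes of 2-fold and 90 of 99 changes of 4-fold, and it made 7 calls among the unchanged. The simulated coding sequences varied independently of each other. These counts therefore do not cover a library that deviates across many coding sequences at once.

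Single coding sequences named in the text had the largest changes among called ones whose libraries did not overlap between the strains, with a mean of at least 20 RPKM in the higher strain. This rule was fixed before the data were examined, and at most 2 per direction and comparison are named because they carry no gene names. Regions were defined after the data were seen, as runs of at least 3 neighbouring coding sequences on the same strand, no more than 300 bp apart, all called in the same direction. The RPKM of a region is its summed reads over its summed coding length. Named regions are the 4 with the largest median log2 fold change per direction among those with at least 20 RPKM in the higher strain. Clustering of calls was tested by moving calls at random over coding sequences in 10000 permutations. Values for comparisons that share the wild-type libraries were set beside 100 simulated data sets with no change. Alternatives were other scalings, filters, pseudocounts, sets of libraries and thresholds, a fit with the replicate number, and, chosen after the data were seen, limma's voom on the recovered reads and all alternatives for regions. Figures were drawn with matplotlib.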

Results

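Transcript levels were measured by RNA sequencing in 3 strains of P. putida KT2440 growing on succinate and glucose together: wild type, a crc mutant and a crcZ crcY double mutant, with 2 libraries per strain. The libraries held 8744531 and 8361292 reads in coding sequences for wild type, 8012230 and 8568702 for the crc mutant, and 8590261 and 7950012 for the double mutant. They listed 5220 to 5246 coding sequences each. Across coding sequences, log2(RPKM + 1) correlated at r = 0.980 to 0.986 between libraries of the same strain and at r = 0.941 to 0.978 between strains. Libraries of the same strain differed by more than counting noise, with a chi-square of 25.9 to 81.8 per degree of freedom, so no pair was the same library listed again. This does not show that they came from separate cultures. Between strains, wild type replicate 2 and crc mutant replicate 1 were the most alike, at r = 0.978 and a chi-square of 76.7 per degree of freedom. The double mutant replicates differed from each other about as much, at r = 0.980 and 81.8. Coding sequences are given by position on the chromosome because the files do not pair them with gene names.

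The comparison of the crc mutant with wild type asks which transcripts depend on Crc when both carbon sources are present. The 5 coding sequences from 640761 to 646092 on the minus strand rose from 6.93 ± 1.12 RPKM in wild type to 69.9 ± 32.4 RPKM in the crc mutant (mean ± SD, n = 2), a 10.1-fold difference of the means. The 9 coding sequences from 4308593 to 4318958 on the plus strand rose 5.07-fold, from 72.7 ± 11.7 to 369 ± 105 RPKM. In the other direction, the 4 coding sequences from 3820915 to 3824958 on the minus strand fell from 806 ± 43.9 to 267 ± 65.5 RPKM. The 5 coding sequences from 1020974 to 1028737 on the minus strand fell from 718 ± 91.2 to 238 ± 73.3 RPKM. By definition every coding sequence of a region passed the test, here with limma adjusted p of 0.00298 to 0.0171, 0.000712 to 0.021, 0.0021 to 0.0191 and 0.0128 to 0.0305 in these 4 regions. Without wild type replicate 1, calls were kept by 3 of 5, 8 of 9, 1 of 4 and 0 of 5 of their coding sequences, and the last region also kept 0 of 5 without crc mutant replicate 2.

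Smaller changes in the crc mutant covered 4 further named regions. The region from 440059 to 443826 on the plus strand, with 4 coding sequences, rose from 117 ± 4.67 to 276 ± 34.7 RPKM. The region from 2809591 to 2812319 on the plus strand, with 3 coding sequences, rose from 629 ± 91.5 to 1256 ± 253 RPKM, close to the threshold at limma adjusted p of 0.0425 to 0.0499. The region from 878470 to 883760 on the plus strand, with 4 coding sequences, fell from 658 ± 113.5 to 269 ± 70.8 RPKM. The region from 6129195 to 6131541 on the minus strand, with 3 coding sequences, fell from 678 ± 166 to 288 ± 39.5 RPKM. In the double mutant these 4 regions had 182 ± 20.1, 1191 ± 112, 641 ± 161 and 253 ± 37.5 RPKM, in the order given. Some of these changes were thus not particular to the crc mutant. Without wild type replicate 1 and without crc mutant replicate 2, none of the coding sequences of these 4 regions kept its call. The regions from 2809591 and from 6129195 also kept 0 of 3 without crc mutant replicate 1, and the region from 2809591 kept 0 of 3 without wild type replicate 2. No coding sequence of the 8 named regions changed sign in these fits, which was likely because they were called from these same libraries. In the region from 440059, for example, the median log2 fold change was 1.11 with all libraries and 1.03 to 1.20 without 1 library of either strain, while the median standard error rose from 0.19 to between 0.24 and 0.26. Among single coding sequences, the largest rise was at 644037 to 645014 on the minus strand, with a log2 fold change of 3.89 ± 0.41 (SE, limma adjusted p = 0.00298). The largest fall was at 3899590 to 3901209 on the plus strand, from 1235 ± 89.2 to 267 ± 1.48 RPKM, a log2 fold change of -2.20 ± 0.19 (limma adjusted p = 0.00121).

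In all, 236 of 5235 tested coding sequences differed between the crc mutant and wild type, 123 higher and 113 lower in the mutant. Of these, 161 differed at least 2-fold and 21 at least 4-fold. With median-of-ratios scaling the split was 100 higher and 138 lower. With the replicate number as a block, 94 were called, 48 higher and 46 lower. Called coding sequences lay side by side more often than calls placed at random: 53 neighbouring pairs on the same strand changed in the same direction, against a mean of 3.32 and a maximum of 13 in 10000 permutations (p = 1e-04, one-sided, the smallest they can give). The permutations treat coding sequences as independent. Neighbours that vary together between libraries would give such pairs too, so this p-value does not bear on a strain effect. The number of calls was lower when a library of either strain was left out. It was 20 without wild type replicate 1, 56 without wild type replicate 2, 130 without crc mutant replicate 1 and 21 without crc mutant replicate 2. The 236 coding sequences had a median absolute log2 fold change of 1.14 with all libraries. In these 4 fits it was 1.03 and 1.26 without wild type replicates 1 and 2, and 1.30 and 1.00 without crc mutant replicates 1 and 2. The median standard error rose from 0.22 to 0.29 without either wild type library and to 0.26 without either crc mutant library. Wild type replicate 1 and crc mutant replicate 2 thus carried more of the difference. Of the 236, 0 changed sign, which was likely because they were selected on these libraries. The count was 589 and 620 without double mutant replicates 1 and 2, which enter the comparison only through the estimate of spread, and 604 without both. The balance of directions moved too, with 53 higher and 77 lower without crc mutant replicate 1 and 14 higher and 7 lower without crc mutant replicate 2. The calls formed 10 regions, but 2 without wild type replicate 1, wild type replicate 2 or crc mutant replicate 2, 3 without crc mutant replicate 1, and 37 and 42 without double mutant replicates 1 and 2.

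**Figure D1:**
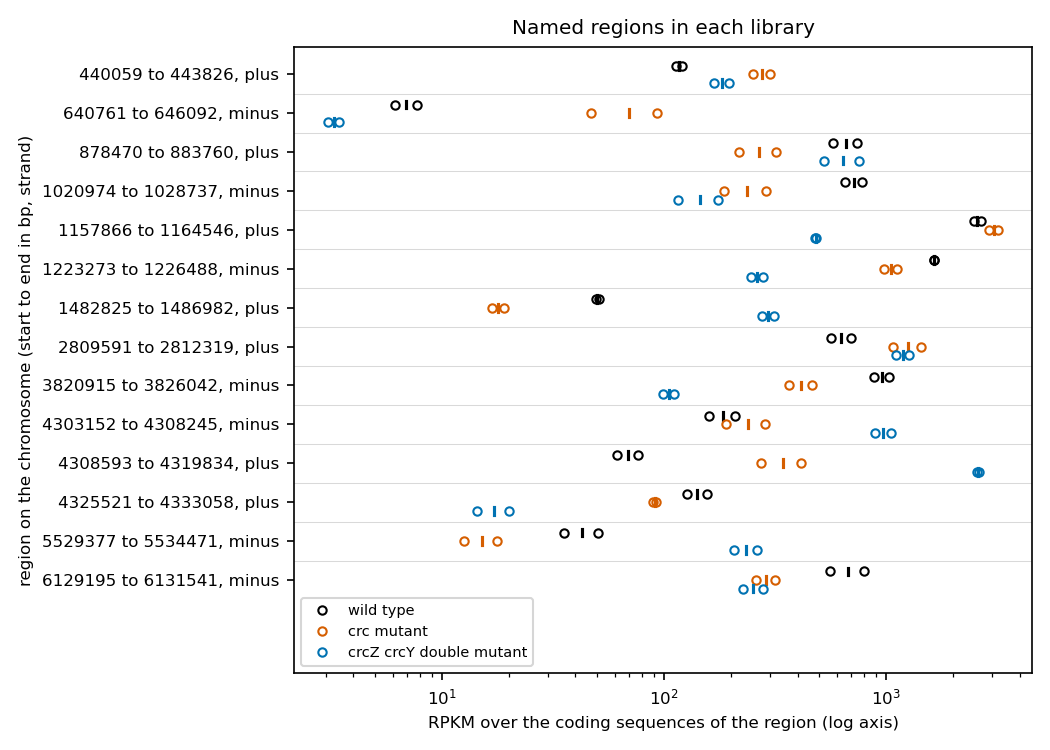
RPKM of each named region of the mutants against wild type, on a log axis, with 1 circle per library (2 per strain) and a vertical bar at the strain mean; rows are regions by start, end and strand. The 10 coding sequences from 4308593 to 4319834 had 69.1 RPKM in wild type, 344 in the crc mutant and 2611 in the double mutant, and those from 1482825 to 1486982 were lowest in the crc mutant and highest in the double mutant.

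The comparison of the double mutant with wild type asks which transcripts change when both small RNAs that counteract Crc are lost. The region that rose in the crc mutant rose further here. Its 10 coding sequences, from 4308593 to 4319834 on the plus strand, went from 69.1 ± 10.8 to 2611 ± 37.1 RPKM, a 37.8-fold difference, with limma adjusted p no higher than 1.86e-05. The 6 coding sequences upstream on the opposite strand, from 4303152 to 4308245, rose from 184 ± 34.9 to 976 ± 113.9 RPKM. The 9 coding sequences from 4325521 to 4333058 on the plus strand fell from 142 ± 20.2 to 17.3 ± 4.07 RPKM. In the crc mutant the first of these neighbouring regions had 238 ± 66.7 RPKM with none of its 6 coding sequences called, and the second had 90.9 ± 1.46 RPKM with 1 of 9 called.

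**Figure D2:**
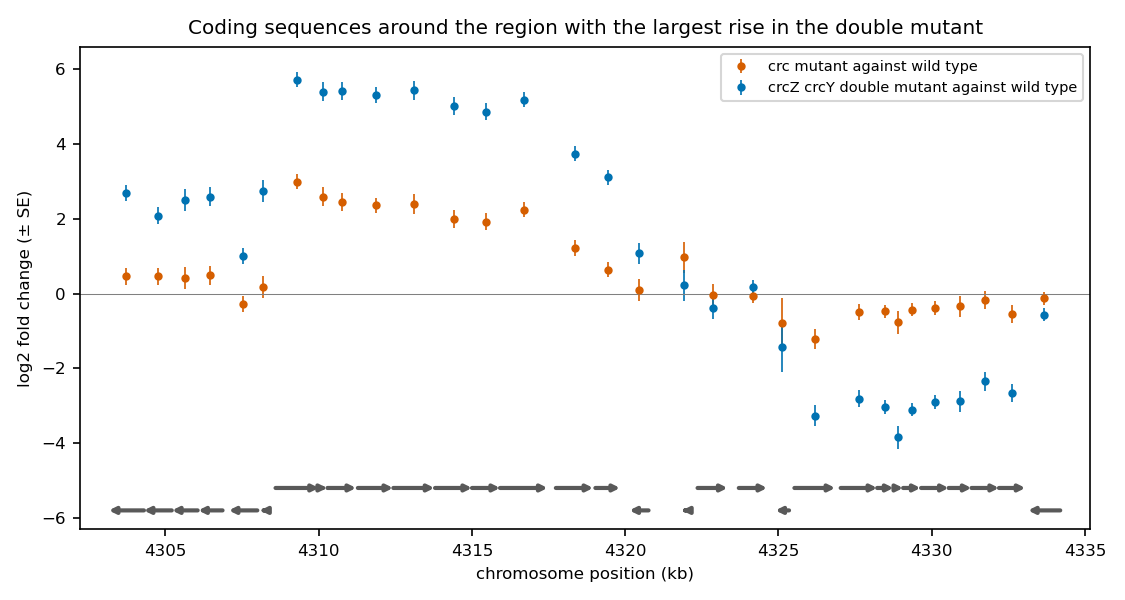
Log2 fold change against wild type, with its standard error, of 31 coding sequences from 4303152 to 4334194, plotted at their midpoints for the crc mutant (orange) and the double mutant (blue), with arrows below showing position and strand. In the double mutant 26 of the 31 were called, and in the crc mutant 10.

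Several abundant transcripts fell in the double mutant. The 6 coding sequences from 1157866 to 1164546 on the plus strand had 2584 ± 144 RPKM in wild type and 484 ± 3.63 RPKM in the double mutant, 5.34-fold lower. The 4 coding sequences from 1223273 to 1226488 on the minus strand had 1649.9 ± 4.12 and 264 ± 23.6 RPKM, 6.25-fold lower. The 5 coding sequences from 3820915 to 3826042 on the minus strand, which include the region that fell in the crc mutant, went from 959 ± 102 to 105 ± 8.96 RPKM, 9.11-fold lower. Within that region the coding sequence from 3821888 to 3823180 had the largest fall among the named coding sequences, from 337 ± 18.7 to 10.6 ± 1.44 RPKM (log2 fold change -4.87 ± 0.19, SE, limma adjusted p = 1.43e-06). Further rises were found from 1482825 to 1486982 on the plus strand (4 coding sequences, 50.1 ± 0.97 to 296 ± 26.7 RPKM) and from 5529377 to 5534471 on the minus strand (5 coding sequences, 42.9 ± 10.5 to 234 ± 39.6 RPKM).

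The double mutant differed from wild type in 504 of 5235 coding sequences, 213 higher and 291 lower. Of these, 338 differed at least 2-fold and 99 at least 4-fold. They formed 35 regions, 10 higher and 25 lower, and 149 neighbouring pairs changed in the same direction against a permutation mean of 15.4 (p = 1e-04, one-sided, the smallest that 10000 permutations can give). Neighbours that vary together between libraries limit this test in the same way. Without wild type replicate 1 there were 182 called coding sequences in 18 regions, and without wild type replicate 2 there were 239 in 19 regions. The 8 named regions were picked from these same libraries for their large changes. No coding sequence in them changed sign without any 1 library of either strain, which this selection made likely. In the region from 4303152, for example, the median log2 fold change was 2.31 to 2.74 in these fits, against 2.56 with all libraries.

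The mutants were then compared with each other, because one lacks the repressor and the other lacks its antagonists. The region from 640761 to 646092 was 69.9 ± 32.4 RPKM in the crc mutant and 3.25 ± 0.28 RPKM in the double mutant, 21.5-fold apart, and 5 of its 5 coding sequences were called. The regions from 1482825 to 1486982 and from 5529377 to 5534471 went the other way. They had 17.9 ± 1.4999 and 15.1 ± 3.58 RPKM in the crc mutant, against 296 ± 26.7 and 234 ± 39.6 RPKM in the double mutant. The 5 coding sequences from 1922251 to 1926862 on the minus strand were also higher in the double mutant, at 176 ± 35.7 against 26.9 ± 9.08 RPKM. Lower in the double mutant were the 3 coding sequences from 1344144 to 1346890 on the minus strand, at 10.5 ± 1.44 against 79.1 ± 6.45 RPKM. The region from 1157866 to 1164546 was 6.33-fold lower in the double mutant than in the crc mutant, where it had 3066 ± 211 RPKM. The region from 4308593 to 4319834 was 7.59-fold higher in the double mutant than in the crc mutant.

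Between the mutants, 491 of 5235 coding sequences were called, 213 higher and 278 lower in the double mutant, with 357 at least 2-fold and 94 at least 4-fold apart. They formed 35 regions, 9 higher and 26 lower. Without crc mutant replicate 2 there were 215 calls, 63 higher and 152 lower, in 19 regions. Without crc mutant replicate 1 the balance turned, with 179 higher and 152 lower. The 8 named regions were again picked from these libraries for their large changes. No coding sequence in them changed sign without any 1 library of either mutant, which this selection made likely. In the region from 1922251, for example, the median log2 fold change was 2.25 to 2.76 in these fits, against 2.53 with all libraries.

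Changes against wild type overlapped between the mutants mainly in the same direction. Of the 10 regions called in the crc mutant, 5 overlapped a region called in the double mutant. All 5 changed in the same direction and 0 in the opposite one, with the wild-type libraries shared. Both mutants were called higher at 51 coding sequences and lower at 42. Independent lists of these sizes would share 5.00 and 6.28, but they leave out the shared wild-type libraries. Simulated strains with no change but the same wild-type libraries shared 0.02 on average. Strains with no change give almost no calls, so this value does not show how much overlap shared libraries add to lists of these sizes. The crc mutant was higher and the double mutant lower at 5 coding sequences, against 6.84 for independent lists, and the reverse held at 10, against 4.60. The simulated value was 0 for both, which is no reference for these counts because strains with no change give almost no calls. These opposite calls included 1159286 to 1160194 on the plus strand, with means of 711 RPKM in wild type, 1379 in the crc mutant and 117 in the double mutant. They also included 1385189 to 1386454 on the minus strand, with 3548, 1241 and 9390 RPKM in the same order. Both were chosen after their values were seen. The counts of 51, 42 and 10 were not recounted without single libraries. They rest on the crc mutant calls, which were fewer without any 1 library of wild type or the crc mutant. The count of 5 was 0 without either wild type replicate 1 or wild type replicate 2, 1 without either crc mutant replicate 1 or crc mutant replicate 2, and 19 and 13 without double mutant replicates 1 and 2.

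Across coding sequences, which are not independent replicates, the log2 fold changes of the mutants against wild type correlated at Pearson r = 0.40 and Spearman rho = 0.43. Simulated strains with no change gave 0.50 and 0.47 because they share the wild-type libraries. The covariance was 0.143, against 0.0435 in the simulation, a difference of 0.0998. With 2 wild-type libraries the controls cannot be divided into sets of 2, so part of the excess overlap may come from the shared libraries.

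**Figure D3:**
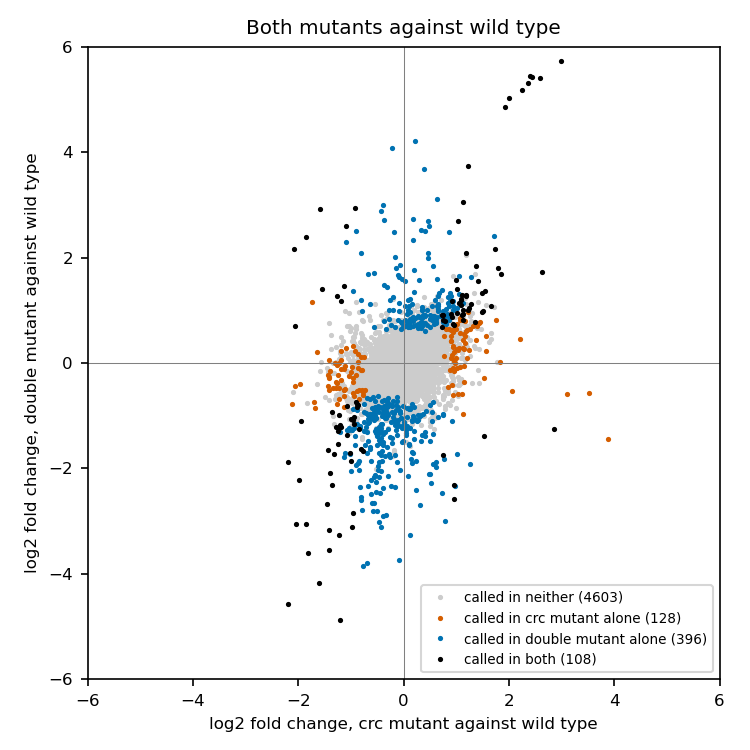
Log2 fold change of each of 5235 coding sequences in the crc mutant (horizontal) and in the double mutant (vertical) against wild type, coloured by where it was called. Of these, 108 were called in both, 128 in the crc mutant alone and 396 in the double mutant alone, and the group at the upper right is the region that starts at 4308593.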

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

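The voom fit, the regions and their alternatives were chosen after the data were seen. The 12 fold changes given by the naming rule kept their call in all 180 values. Of 264 values of the 24 named regional differences, 20 moved beyond the replicate SD. No sign changed. The kept calls and signs came largely through selection on these same libraries and settings that leave the fold unchanged. Counts of calls between the crc mutant and wild type were 204 to 238 with other scalings, filters and pseudocounts or without the 20 most abundant coding sequences, 161 at a log2 fold change of at least 1 and 318 with voom. Fitting only the 4 samples compared gave 604 in place of 236. The fold changes are the same, so this came through the estimate of spread and its degrees of freedom. The median standard error of the 236 was 0.207 in place of 0.218, which was not shown to account for it alone. Without 1 library at a time the count ran from 20 (without wild type replicate 1) to 620 (without double mutant replicate 2); it was 21 without crc mutant replicate 2, 56 without wild type replicate 2, 130 without crc mutant replicate 1 and 589 without double mutant replicate 1. The range was 182 (without wild type replicate 1) to 523 for the double mutant against wild type, with 239 without wild type replicate 2, and 215 (without crc mutant replicate 2) to 701 between the mutants. Such fits have fewer samples and assume that a lone library varies like other strains. The correlation ran from 0.30 to 0.51. The count of 5 coding sequences higher in the crc mutant and lower in the double mutant ran from 0 (without wild type replicate 1 or wild type replicate 2) to 19 (without double mutant replicate 1), with 1 without either crc mutant replicate and 13 without double mutant replicate 2. The counts of regions (10, 35 and 35 by comparison) ran from 2 (without wild type replicate 1, wild type replicate 2 or crc mutant replicate 2) to 42 (without double mutant replicate 2), from 18 (without wild type replicate 1) to 32, and from 19 (without crc mutant replicate 2) to 40. Gaps of at most 50 bp gave 6, 22 and 23. For the crc mutant against wild type, 17 regions were called with voom and 36 from the 4 samples compared. Of its 8 named regions, 0 kept every call in all fits without 1 library, and 5 lost all calls in at least 1.

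Strains share replicate numbers, but the labels do not say that these mark a batch. With the replicate number as a block, 94, 356 and 358 coding sequences were called in place of 236, 504 and 491, and the count of 5 became 1. Regions numbered 3, 26 and 29, and 3, 8 and 8 of the 8 named regions per comparison kept every call. Deviations of same-numbered libraries correlated at 0.23 between the crc mutant and wild type, -0.19 between the double mutant and wild type and -0.34 between the mutants.

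The count model planned for deposited counts was not run. The fixed gene lists and the Crc motif search were not run, for want of names and a genome. Depth limits the 165 to 235 coding sequences per library with under 10 reads.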

Other observations

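The comparison of library splits, the lowest ratio between single libraries and the marker test below were chosen after the results were seen, as were the regions described here. In the double mutant, 2 neighbouring regions on opposite strands fell together. The 4 coding sequences from 4761342 to 4767786 on the plus strand went from 338 ± 83.3 RPKM in wild type to 31.6 ± 10.4 RPKM (mean ± SD, n = 2), and the 6 from 4767855 to 4796442 on the minus strand went from 52.2 ± 8.80 to 7.40 ± 1.49 RPKM. In the crc mutant they had 217 ± 18.3 and 29.4 ± 1.88 RPKM, with 0 of 4 and 1 of 6 coding sequences called against wild type. A run of 7 coding sequences from 2800655 to 2807592 on the plus strand fell from 108 ± 8.38 to 30.97 ± 2.90 RPKM. Among abundant transcripts, the 3 coding sequences from 1304138 to 1307615 on the minus strand fell from 2333 ± 181 to 992 ± 213 RPKM, but kept 1 of 3 calls without wild type replicate 1 and 0 of 3 without wild type replicate 2, with median log2 fold changes of -1.16 to -0.94 without 1 library against -1.04 with all. The run of 7 kept 5 calls without wild type replicate 1, while the neighbouring pair kept every call without any 1 library of either strain.

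The 5 coding sequences from 1758834 to 1762839 on the plus strand had 21.7 ± 2.30 RPKM in wild type, 43.4 ± 1.24 in the crc mutant and 47.0 ± 1.05 in the double mutant. All 5 were called in the double mutant and 2 in the crc mutant against wild type, and 0 between the mutants. Without either wild type replicate 1 or wild type replicate 2, 1 of the 5 kept its call in the double mutant, and without double mutant replicate 2 there were 2. The median log2 fold change stayed between 0.93 and 1.17 without 1 library, against 1.09 with all, while its median standard error rose from 0.22 to between 0.27 and 0.28. Of the 278 coding sequences lower in the double mutant than in the crc mutant, 203 had a wild-type level nearer to the crc mutant (73.0%), and of the 213 higher ones 119 did (55.9%). These sets were selected on the difference between the mutants, and the shares were not tested.

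The fold changes of both mutants against wild type had a positive covariance beyond what shared libraries give in simulation. With each mutant set against a different wild-type library, the lower of both covariances was 0.0851 ± 0.0205 (standard error over chromosome blocks). The other was 0.121, so a positive covariance did not need the same library in both fold changes. The standard error measures spread along the chromosome and not between libraries. A deviation common to both wild-type libraries would also remain, so the wild-type libraries as the whole cause stay open. Without the coding sequences in regions called in either mutant against wild type, the covariance less the part from shared libraries was 0.0649 ± 0.0089 over 5065 coding sequences, which argues against these regions as the whole cause. A marker or growth difference common to both mutants, and a response to the loss of either part of the system, were not tested and stay open.

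The region from 4308593 to 4319834 rose in both mutants, although 1 lacks the repressor and the other its antagonists. The lowest ratio of any mutant library to any wild-type library was 3.58, so a single low wild-type library does not account for it. The median log2 fold change in the crc mutant was 2.29 with median-of-ratios scaling and 2.30 with scaling to total reads. A tet marker effect of equal size in both mutants is argued against by their difference of 2.95 ± 0.27 on the log2 scale, but the marker sits in different genes, so an effect of unequal size may remain and is confounded with the strains. No biological explanation was tested.

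The number of calls between the crc mutant and wild type fell when a library of either strain was left out. Standard errors of the 236 rose about equally for both libraries of a strain, but the fold changes did not move alike. Their median absolute log2 fold change was 1.03 without wild type replicate 1 and 1.00 without crc mutant replicate 2. It was 1.26 without wild type replicate 2 and 1.30 without crc mutant replicate 1. Of the 236, 0 changed sign, which was likely because they were selected on these libraries. After all libraries were thinned to 7950012 reads, the count was 262 in the first of 5 thinnings and 201 to 262 over all 5, and the lowest count without 1 library was 15 at most, so unequal depth accounts for neither. Variation between replicates along the axis that separates the strains stays open. The double mutant replicates enter neither strain mean. Their difference correlated across coding sequences with the difference of crc mutant and wild type at r = 0.20 ± 0.026 (standard error over chromosome blocks). This r lies between the bounds of 0.1 and 0.3 set beforehand. Its standard error measures spread along the chromosome and not between libraries. No biological explanation was tested for this pattern.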
